A study of Mus musculus with 6 samples.

How the data were processed

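The series holds 6 samples in 3 groups, WT zygotes, WT 2-cell embryos and Pabpn1l-null zygotes, with 2 samples each. Per the labels' protocols, 50 zygotes per sample were labelled with S4U, ribosomal RNA was depleted, RNA was alkylated with iodoacetamide, and libraries were sequenced. Reads were aligned to mm10, per the submitters' processing notes. The aligner, the counting tool, the annotation and the handling of duplicate reads are not given in the sources used here. The deposited table gives, per row and group, a count of reads and a count of reads with a T-to-C mismatch, made by the authors, and a Positive or Negative call. It has 1 pair of count columns per group, and whether a pair merges both samples of its group is not given in the sources used here. No other table of values per sample was used here.

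The table has 30493 rows and 23259 gene names. For 47 rows a date stands in place of a name, and these were left out. Rows that repeat another row of the same gene with the same values numbered 6131, and 928 genes had 2 or more distinct rows. The row with the most reads was kept per gene, which left out part of all reads (all rows hold 4168929, 1749879 and 5439737 in WT zygotes, null zygotes and 2-cell embryos). Of the names, 20683 are RefSeq symbols, and 23042 are symbols or synonyms. In 19 sets, different names with at least 200 reads share the same values in all columns. Coordinates are those of RefSeq on GRCm38, the assembly that mm10 represents.

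The comparisons, 18 gene lists, the rule for named genes, the RLE and filter alternatives, TMM scaling and the adjusted p threshold were fixed before the data were examined. The planned edgeR quasi-likelihood, DESeq2, limma-voom, camera and fry tests, the replicate block and the omission of single libraries need replicates and could not be run on 1 column pair per group. The exact conditional binomial test took their place after the table was seen. It compares libraries, not conditions. Gene-list medians were set beside 10000 random lists of the same size drawn from 10 bins of expression, for the 15 lists with at least 5 tested members.

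Columns were scaled by TMM factors (0.996, 1.04 and 0.963 for WT zygotes, null zygotes and 2-cell embryos) on total reads, and T-to-C reads used the same factors. The test was run on reads at the start, and 2670 genes in total reads and 783 in T-to-C reads passed at the same thresholds in null against WT zygotes. The low counts of the null column were then seen to come in clumps, and 7 reads were counted as 1 molecule in every column. This rule, the demand of a 2-fold difference beside an adjusted p under 0.05, and the 0.5 molecule added before a log2 ratio and scaled to column size were chosen after those values were seen. An unscaled addition was tried and replaced, because it biased log2 ratios of low genes between columns of different depth. With 7 reads per molecule 155 genes in total reads and 2 in T-to-C reads passed. P values were adjusted by the Benjamini-Hochberg method.

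Genes were tested with at least 20 reads over the 3 columns for total reads, at least 10 for T-to-C reads, and at least 20 in both columns for the T-to-C share. Intervals are exact 95% Clopper-Pearson intervals on molecules, except for shares of whole columns, which use reads. Ratios against 0 are given as at least a fold, taken at a floor of 3 molecules, or 21 reads, in the column at 0. These bounds hold the other count fixed, so they lie above the lower ends of the 2-sided intervals. Summed reads of a list cover all its members in the table, tested or not. Sums without the member that moves them most were added after the sums were seen. Share ratios were resampled over genes 1000 times, with fewer draws for whole columns, genes outside the class labelled at the 2-cell stage and genes outside the oocyte-expressed list. Thinning, splits and simulated columns used 100 draws. Columns simulated to check the test were all drawn in clumps of 7 reads, although the WT columns showed no such clumps. In simulated unchanged columns 1, 3 and 1 genes were called in total reads and 0 in T-to-C reads, in null against WT zygotes, 2-cell embryos against WT zygotes and null zygotes against 2-cell embryos.

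Depth was 3001473, 1270347 and 4020443 reads on named genes in WT zygotes, null zygotes and 2-cell embryos, with at least 10 T-to-C reads for 1909, 1254 and 2689 genes. The 10 genes with the most reads held 7.45%, 8.21% and 11.1% of reads. RLE factors were 1.06, 1.11 and 0.852. In null against WT zygotes the median log2 ratio of all genes was -0.10 with column totals, -0.15 with TMM and -0.16 with RLE.

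Named genes are Pabpn1l, the 10 highest and 10 lowest ratios past the threshold per comparison with WT zygotes (5 and 5 in null zygotes against 2-cell embryos) at a level above the median, without predicted or unnamed genes and pseudogenes, up to 4 members per list, and 5 genes per direction past in both comparisons. The demand that replicates not overlap could not be applied. Other genes were chosen after their values were seen, and the text says so or gives them as members of a list. The lists cover early 2-cell genes, major genome activation, ribosome biogenesis, oocyte-expressed genes, decay machinery, RNA polymerase II, p53 targets, DNA damage response, H3K4 and H3K27 modifiers, immediate early genes, spliceosome, histones, ribosomal proteins, mitochondrial mRNAs, abundant non-coding RNAs, and markers of cumulus, sperm and blood cells. Of 716 list entries 710 were matched to the table.

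Alternatives were RLE factors, column totals, T-to-C reads scaled by their own total, 2 filters, adjusted p alone, omission of abundant non-coding or of predicted genes, the sum of distinct rows, other assumptions on clumps, and edgeR's exact test on reads at an assumed biological coefficient of variation of 0.4. Tools were Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16.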

Results

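Newly made and stored RNA were measured in mouse embryos by metabolic labelling. 4-thiouridine is a uridine analogue that living cells build into RNA during transcription, and alkylation with iodoacetamide makes its positions read as T-to-C mismatches. Reads with such a mismatch, called T-to-C reads here, include those of RNA made during the labelling. Without an unlabelled control, an unknown part of them comes from sequencing error or sequence differences. Per the labels, wild-type (WT) zygotes, WT 2-cell embryos and zygotes of the genotype Pabpn1l-null were collected, with 2 samples per group, 50 embryos per sample and 2 h in 200 μM label from 26 h after the hormone injection that triggers ovulation. The protocol text is the same for all 6 samples and speaks of zygotes alone, and the collection time of the 2-cell embryos is not given in the sources used here. PABPN1L is a poly(A)-binding protein of oocytes and early embryos that works with BTG4 and the CCR4-NOT deadenylase in the decay of maternal mRNA. The series title links this decay to early transcription, so the comparisons below ask what differs when Pabpn1l is lost, what differs between the zygote and the 2-cell stage, and whether these differences are shared.

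The table holds 1 pair of columns per group, total reads and T-to-C reads, so the 2 samples of a group cannot be compared and no difference has a replicate check. Every test below compares 3 sets of libraries, not 3 conditions. The WT zygote column held 3001473 reads on named genes, of which 90945 were T-to-C reads. In the Pabpn1l-null zygote column 48987 of 1270347 reads were T-to-C reads, and in the WT 2-cell column 182594 of 4020443. At least 1 read was counted for 14157, 9773 and 14088 genes in the same order, and at least 10 reads for 9544, 7676 and 10909. A count of 0 was taken to allow up to 3 molecules, or 21 reads, in any column. These floors and all intervals cover counting error only, since reads copied by PCR without molecular identifiers are not independent molecules.

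Reads of the null column came in clumps. Of 969 genes for which the WT zygote level predicted 3 to 5 reads, 54.9% had none in the null column, against 2.08% if each read were drawn independently. With both WT columns thinned to the null total, 1436 genes of the WT zygote and 1073 of the 2-cell embryo had exactly 1 read, against 184 in the null column. The zeros of the null column corresponded to 6.63 to 7.66 reads per molecule over 5 ranges of level. This estimate assumes that each gene has the same level in both zygote columns. Genes truly lost in null zygotes would raise the estimate and so make their own difference harder to detect. Reads of every column were divided by 7 before the tests, although the WT columns showed no such deficit of genes at 1 read.

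**Figure D1:**
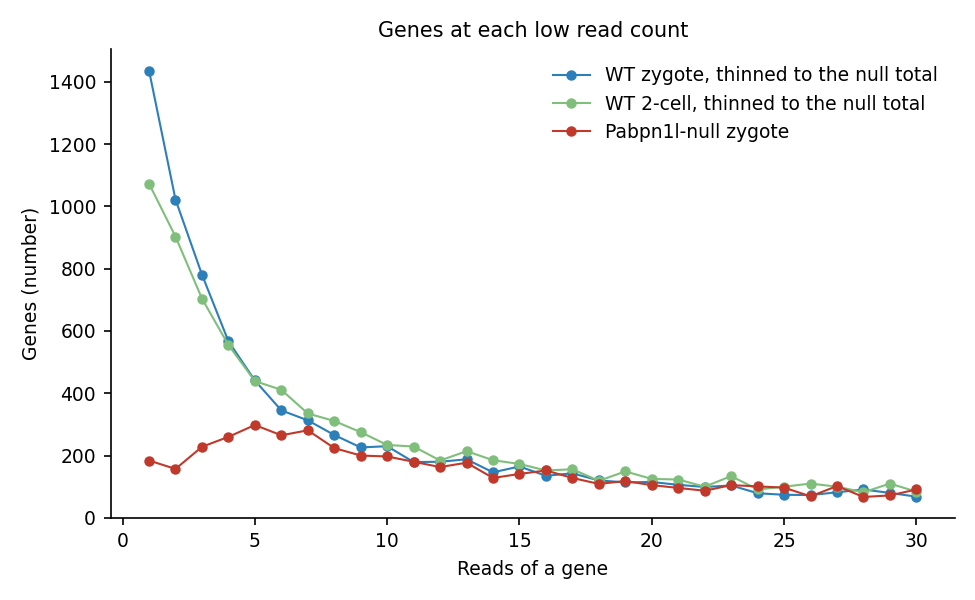
Number of genes (vertical axis) at each read count of a gene from 1 to 30 (horizontal axis), for the null column as deposited and both WT columns thinned to its total. At 1 read the null column holds 184 genes, against 1436 in the WT zygote and 1073 in the WT 2-cell column.

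Pabpn1l itself, on chromosome 8 at 122619471 to 122622735 of GRCm38, had 47 reads in WT zygotes, 4 in null zygotes and 14 in 2-cell embryos. None of them was a T-to-C read. The null-to-WT ratio was 0.192 with an upper end of 2.24, so the lower level in the library labelled null was not beyond counting error. The deleted part of the gene is not given in the sources used here, and the table counts whole genes.

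Few genes differed in T-to-C reads between null and WT zygotes. Gdf9, an oocyte-secreted growth factor of the TGF-beta family on chromosome 11 at 53430774 to 53437904, had 149 T-to-C reads in WT and 269 in null zygotes, a ratio of 4.08 (95% interval 2.34 to 7.28). Rn45s, the precursor of ribosomal RNA, had 1097 and 1699, a ratio of 3.50 (2.85 to 4.30). Both were also higher in total reads, Gdf9 by 2.63 (2.42 to 2.86) and Rn45s by 6.52 (5.85 to 7.28). For Rn45s the share of T-to-C reads was lower, 19.1% against 35.6%, and ribosomal RNA had been depleted from these libraries. The T-to-C share of Gdf9 was 1.96% in WT and 3.04% in null zygotes and did not pass the share test, so its T-to-C reads are not shown to be more new RNA per transcript. Furin, a protease that matures secreted proteins, had 2 T-to-C reads in WT and 64 in null zygotes and did not pass the test. Of 4376 genes tested by the exact conditional binomial test (Benjamini-Hochberg adjusted p under 0.05 and at least 2-fold), 2 were higher in null zygotes and 0 lower, with 39 at an unadjusted p under 0.05. In simulated data for this comparison, 100 genes were changed per fold size and both columns were drawn in clumps of 7 reads. The test recovered 3% of 4-fold and 1% of 2-fold changes, so most differences of these sizes were not detectable with 7 reads counted as 1 molecule. With edgeR's exact test on reads at an assumed biological variation of 0.4, 1 gene was called and both Gdf9 and Rn45s lost the call, while with every read counted as 1 molecule 783 genes passed, and with clumps assumed in the null column alone 9.

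Total reads differed for more genes. Higher in null zygotes were Txndc11, a thioredoxin-domain protein (ratio 10.02, 2.29 to 77.7), Vwa2 (7.71, 2.69 to 27.3), the receptor phosphatase gene Ptprf (7.18, 2.21 to 30.3), Fam134c (6.08, 2.26 to 18.9), the mitochondrial ribosomal protein gene Mrpl14 (5.74, 1.97 to 19.8), the amino acid transporter gene Slc36a1 (4.76, 1.93 to 12.9), Furin (4.71, 3.33 to 6.73) and the endophilin gene Sh3gl1 (4.54, 2.32 to 9.29). Lower were Atp6v1g1, a subunit of the proton pump of lysosomes (0.0696, 0.00537 to 0.304), Lin52, a subunit of the cell-cycle repressor complex DREAM (0.101, 0.00493 to 0.515), and Sec62, a component of protein import into the endoplasmic reticulum (0.127, 0.0291 to 0.365). Txnip, the thioredoxin-interacting protein, had 3839 reads in WT and 340 in null zygotes (0.200, 0.146 to 0.269). Fnip1, Cwf19l2, Zfp120, Gnai1, Zfp229 and the mitotic chromatin factor Cdca2 lay between 0.143 and 0.220. Of 11262 genes tested, 78 were higher and 77 lower, where 35% of simulated 4-fold and 3% of 2-fold changes were recovered. Under edgeR's exact test at the assumed variation 137 genes were called, 25 higher and 112 lower, of which 4 were among these 155, and of the genes named here Atp6v1g1 alone kept its call. With every read counted as 1 molecule 2670 genes passed, and with clumps assumed in the null column alone 311.

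Oocyte-expressed maternal genes differed in both directions between null and WT zygotes. Of 45 tested members 6 were higher and 2 lower in total reads, and 8 and 2 adjusted over the list alone. Among the higher were Gdf9 and 2410004A20Rik (5.85, 3.92 to 8.92), and lower were Elavl2, an RNA-binding protein gene (0.391, 0.288 to 0.523), and Nlrp4f (0.462, 0.360 to 0.586). The median log2 ratio was 0.07, percentile 96.8 among 10000 random lists matched on level, inside their central 95%. The summed reads gave a ratio of 1.12 (1.09 to 1.15), which rests on Gdf9, since it was 0.991 (0.960 to 1.02) without it. Summed T-to-C reads of the list gave 1.40 (1.22 to 1.60), or 1.30 (1.13 to 1.49) without Gdf9, with 1 of 36 members higher and 0 lower. The T-to-C share of the whole null column was also higher than in WT zygotes (ratio 1.27), so a rise in T-to-C reads is not particular to this list. For the maternal mRNA decay machinery 2 of 34 were higher and 2 lower. Dcp1a, a decapping activator (2.74, 2.40 to 3.13), and Lsm14b, a repressor of translation in oocytes (2.42, 2.01 to 2.92), were higher, and Cnot2, a CCR4-NOT subunit, was lower (0.452, 0.259 to 0.748). The median was -0.12 (percentile 50.5), while the summed ratio was 1.19 (1.12 to 1.26), and 0.985 (0.923 to 1.05) without Dcp1a.

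Among tested genes of genome activation, the chaperone gene Hspa8 alone was called higher in null zygotes in total reads. Among 33 tested members of the list of early 2-cell genes 0 were higher and 1 was lower in total reads, Arg2 (0.399, 0.212 to 0.701), with a median of -0.27 (percentile 13.6), or 0 when the 13 members with no read in 1 column were set at their bound. Summed reads of the 35 members in the table were 1445 in WT and 279 in null zygotes, a ratio of 0.436 (0.303 to 0.615). Dux, a transcription factor gene that starts the 2-cell program, had 150 and 13 reads (0.196, 0.0198 to 0.832) and did not pass. Of 31 genes of major genome activation Hspa8 was higher (3.93, 1.70 to 9.64) and the histone chaperone gene Nasp lower (0.253, 0.0943 to 0.568), with a median of -0.07 (percentile 54.2). Summed total reads of this list gave 0.886 (0.827 to 0.949), but 1.24 (1.13 to 1.35) without Klf17, so 1 gene sets the direction of the sum. In T-to-C reads 0 of 25 early 2-cell genes and 0 of 16 genes of major genome activation passed, with summed ratios of 0.622 (0.0986 to 2.53) and 1.05 (0.644 to 1.68).

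Cytosolic ribosomal protein genes were the list that stood farthest from random lists in null zygotes. Their median log2 ratio of total reads was 0.75 over 36 tested members, against -0.20 for random lists (percentile 100), and their summed reads of 1589 in WT and 1103 in null zygotes gave 1.57 (1.27 to 1.93). No single member passed the test, and Rpl15 had a ratio of 1.63 (0.873 to 2.99). In T-to-C reads the 9 tested members had a median of 1.35 (1.07 at the bound, percentile 99.2), and 0 passed. With no filter on low counts the median was 0 and the list no longer stood apart, while 1 other list did. Reads of these genes may be shared with their many pseudogenes. Ribosome biogenesis genes had a median of -0.47 (percentile 5.29), or -0.21 with 4 members at their bound, and 1 of 37, Wdr43, was lower (0.284, 0.124 to 0.573). In the p53 target list 1 of 27 was lower, Trp53inp1 (0.346, 0.214 to 0.537), with a median of 0 (percentile 86.4). In the DNA damage response machinery 1 of 33 was higher, the single-strand DNA-binding subunit Rpa1 (2.08, 1.45 to 2.96), with a median of 0.03 (percentile 83.8) and a summed ratio of 0.916 (0.831 to 1.01) in the opposite direction.

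No member passed in either direction among 40 genes of RNA polymerase II and elongation (median -0.20, percentile 24.1), 27 modifiers of H3K4 and H3K27 (-0.01, 67.2), 16 immediate early genes (-0.19, 48.0, with a summed ratio of 1.01 in the opposite direction), 32 genes of the spliceosome core (-0.03, 67.7) and 57 replication-dependent histones (-0.06, 68.3). Of 25 small nuclear, nucleolar and other abundant non-coding RNAs Rn45s alone was higher, with a median of 0 (percentile 93.7) and a summed ratio of 5.37 (4.86 to 5.94) that rests on Rn45s. Markers of other cells were low. The 25 markers of cumulus and granulosa cells in the table summed to 315 reads in WT zygotes, 83 in null zygotes and 440 in 2-cell embryos, and of 6 tested 0 differed between the zygotes. The 15 sperm markers in the table summed to 454, 274 and 1829 reads in the same order, nearly all from Odf2, and of 3 tested 0 differed. Laptm5, the 1 tested blood cell marker, had 42, 1 and 23 reads. Counts of genes past the test adjusted over the list alone equalled those over all genes for each list other than the oocyte-expressed one, in both total and T-to-C reads.

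**Figure D2:**
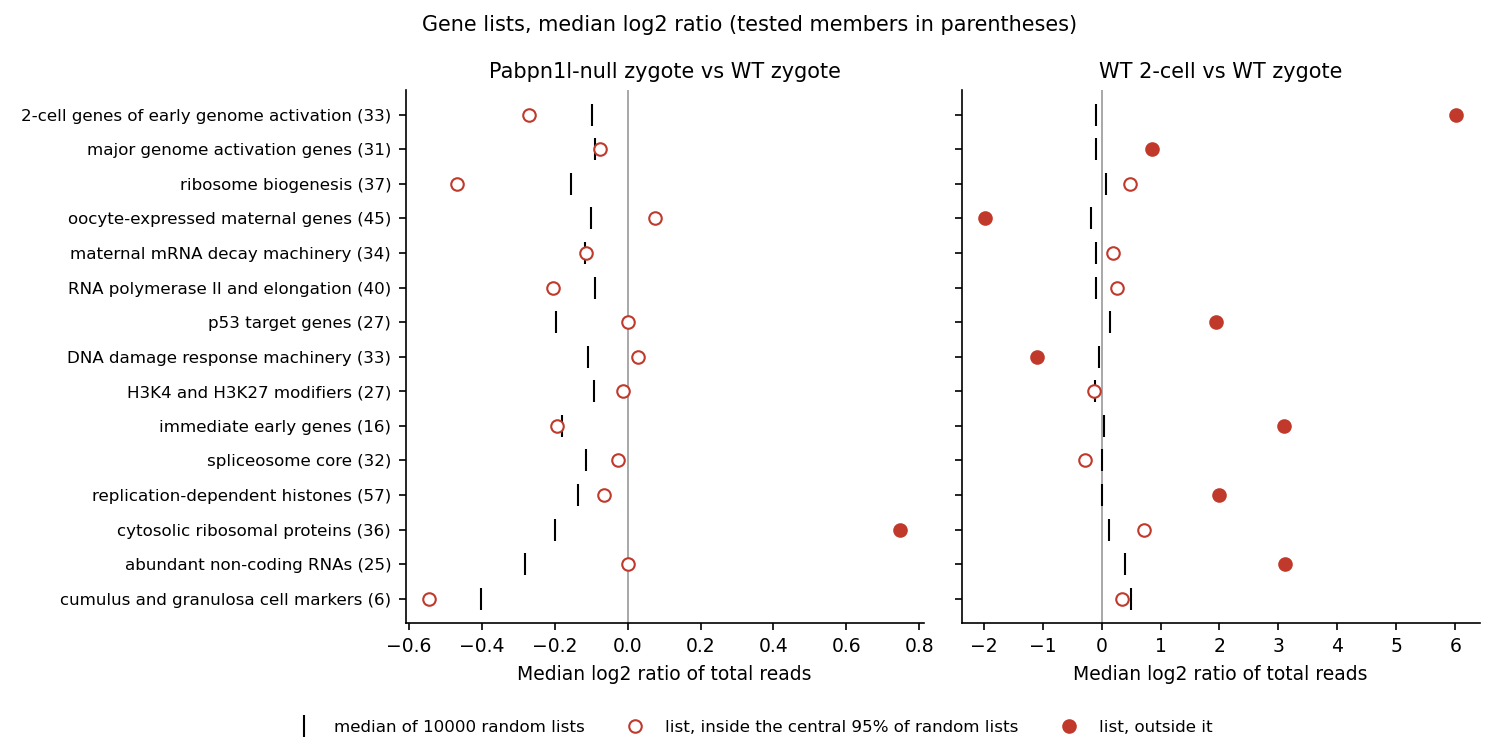
Median log2 ratio of total reads (horizontal axis) of 15 gene lists with at least 5 tested members (vertical axis, number tested in parentheses), for null against WT zygotes (left) and 2-cell embryos against WT zygotes (right). Circles are lists, filled where they lie outside the central 95% of 10000 random lists, and black ticks are the random lists' medians. Cytosolic ribosomal proteins (0.75) are the filled circle on the left, and early 2-cell genes (6.01) lie farthest to the right on the other side.

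Among the genes with the highest ratios of T-to-C reads in 2-cell embryos against WT zygotes were RNase P, histone and early 2-cell genes. Rpph1, the RNA subunit of RNase P on chromosome 14 at 50807447 to 50807771, had 32 T-to-C reads in WT zygotes and 7825 in 2-cell embryos, a ratio of 189 (77.8 to 623), and its T-to-C share was 6.0% and 56.3%. Rprl3, a copy of the same RNA, had 0 and 1079, at least 39.7-fold higher. The histone genes Hist2h2bb (4 and 1474 reads) and Hist1h4d (0 and 296, at least 10.9-fold), Prps1l3 (131, lower end 27.5), Tdpoz4 (at least 10.7-fold), the deubiquitinase gene Dub1a (at least 8.12-fold), Tdpoz1 (at least 5.44-fold), the phosphate transporter gene Slc34a2 (at least 5.07-fold) and Arhgap19 (2 and 249 reads) were also higher. Lower T-to-C reads were found for Bcl2l10, a Bcl-2 family member (0.0427, 0.0127 to 0.108), the homeobox genes Obox1 (98 and 5 reads) and Obox2 (84 and 2), Slbp, which binds histone mRNA (104 and 6), Fam46c, a poly(A) polymerase gene (0.0760, 0.0276 to 0.172), and Zfp57, a keeper of imprints (0.0789, 0.0255 to 0.192). Gpr1, Rgs2, Acbd3 and Bpgm were lower as well. The T-to-C share was higher for 128 and lower for 4 of 3901 genes tested. Most falls in T-to-C reads are therefore not shown to exceed the fall in total reads.

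Of 4376 genes, 189 were higher and 71 lower in T-to-C reads at the 2-cell stage, or 72.7% higher. In columns simulated with clumps 3% of 4-fold changes were recovered. The split was 84.1% with RLE factors and 48.7% when T-to-C reads were scaled by their own total, so the balance of directions depends on the scaling. It also depends on the filter, since with 50 reads in at least 2 columns 36 genes were higher and 51 lower (41.4% higher). This filter leaves out genes that reach 50 reads in 2-cell embryos alone but keeps those that reach it in both zygote columns. It thus favours lower calls by its design. Rgs2 and Acbd3 lost the call with RLE factors, and with edgeR's exact test at the assumed variation 938 genes were called, 215 of them among these 260. With clumps assumed in the null column alone, 1327 genes were higher and 831 lower, since reads of both WT columns then count as molecules. Reads of the Tdpoz, Dub and Usp17l, Zscan4 and histone families, and of Rpph1 and Rprl3, may be shared between near-identical copies, so their single members are uncertain.

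In total reads, 2-cell embryos held transcripts hardly seen in zygotes. Tdpoz5 had 1 read in WT zygotes and 3670 in 2-cell embryos, the arginine methyltransferase gene Prmt6 had 1 and 2356, the nucleotide synthesis gene Prps1 had 1 and 1912, and the transcription factor gene Sp6 had 1 and 1683. Tdpoz4 (at least 98.5-fold), Rprl3 (at least 76.9-fold), Tdpoz1 (at least 45.0-fold), Unc119b (at least 38.1-fold), Dub1a (lower end 63.7-fold) and Zfp352 (lower end 74.1-fold) were also higher. Lower were Xdh, xanthine dehydrogenase (at least 29.9-fold), Fbxw26 (at least 22.1-fold), Lypd3 (at least 19.2-fold), the meiotic kinase gene Aurkc (at least 15.7-fold), Sh3rf2 (at least 9.07-fold) and Atpbd4 (905 reads and 1), with Zfp169, Extl1, Ttc4 and the calcium channel gene Itpr2 under 0.02. Of 11262 genes 1843 were higher and 1804 lower. In columns simulated with clumps 48% of 4-fold and 10% of 2-fold changes were recovered. The split was 50.5% higher with TMM factors and 61.2% with RLE factors, which moved the median log2 ratio of all genes from 0.04 to 0.28. With the filter of 50 reads, which leaves out genes that reach them in 2-cell embryos alone, 773 genes were higher and 1484 lower (34.2% higher). With clumps assumed in the null column alone 6644 genes passed. Under edgeR's exact test at the assumed variation 2966 genes were called, 1736 higher and 1230 lower, of which 1964 kept the call made here.

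Early 2-cell genes were higher as a group. Of 33 tested members 28 were higher and 1 lower, Arg2 (0.319, 0.208 to 0.481), and 28 and 2 adjusted over the list alone. Their median log2 ratio was 6.01 (percentile 100), or 4.36 with 13 members at their bound, and the summed ratio was 16.7 (14.6 to 19.3), or 27.7 (23.2 to 33.4) without Arg2. Dux had 150 and 84 reads (0.432, 0.194 to 0.917) and did not pass. In T-to-C reads 4 of 25 were higher and 0 lower, or 8 and 0 adjusted over the list alone, with a summed ratio of 17.7 (9.40 to 37.6), or 28.9 (13.1 to 79.6) without Arg2. The T-to-C share of this list was 4.78% (2.30 to 8.64) in WT zygotes and 5.04% (4.42 to 5.72) in 2-cell embryos. Its T-to-C reads thus rose with its total reads, and no rise in share was seen. Immediate early genes, which respond first to growth signals, had a median of 3.09 (2.91 at the bound, percentile 100). Of 16, 9 were higher and 1 lower, or 10 and 1 adjusted over the list alone, with Jund at 10.1 (5.85 to 18.9), Junb at 7.68 (3.33 to 21.8) and the phosphatase gene Dusp1 at 0.240 (0.102 to 0.515).

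Replication-dependent histones were higher in 31 and lower in 1 of 57 members, with a median of 1.99 (1.85 at the bound, percentile 100). Hist1h3e stood at 72.1 (42.6 to 133) and Hist1h3f at 0.237 (0.205 to 0.274). Summed T-to-C reads of the histones gave 11.97 (9.07 to 16.1), with 11 of 34 higher and 0 lower, or 12 and 0 adjusted over the list alone, and their T-to-C share was 1.19% in WT zygotes and 8.68% in 2-cell embryos. In p53 targets 9 of 27 were higher and 0 lower, or 10 and 0 adjusted over the list alone, with a median of 1.93 (0.91 with 4 members at the bound, percentile 100). Sesn2, a stress-induced sestrin, had 16 and 1096 reads (52.9, 15.5 to 362) and the cell-cycle inhibitor gene Cdkn1a 32 and 245 (5.91, 2.23 to 20.6). With the filter of 50 reads in at least 2 columns the median of the p53 targets was 0.50 and no longer stood apart from random lists. Members that reach 50 reads in 2-cell embryos alone are left out by this filter. Abundant non-coding RNAs were higher in 10 and lower in 0 of 25, or 11 and 0 adjusted over the list alone, with a median of 3.10 (1.83 with 10 members at the bound, percentile 100). Rn45s had a ratio of 47.5 (43.2 to 52.3), in libraries from which ribosomal RNA had been depleted. The T-to-C share of the whole list was 29.3% in WT zygotes and 7.27% in 2-cell embryos. Without Rn45s it was 4.86% and 48.9%, so the T-to-C reads of Rn45s did not rise as much as its total reads.

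Oocyte-expressed genes were lower in 2-cell embryos. Of 45 members 1 was higher, Omt2b (2.72, 1.68 to 4.58), and 33 were lower, with a median of -1.97 (percentile 0) and a summed ratio of 0.341 (0.331 to 0.352). Ooep, a subunit of the subcortical maternal complex, stood at 0.0732 (0.0494 to 0.105). In T-to-C reads 3 of 36 were higher and 10 lower, or 3 and 12 adjusted over the list alone, with Omt2b (2 and 95 reads) and Oosp1 (11.9, lower end 1.84) higher. Genes of major genome activation had a median of 0.85 (percentile 99.48), with 10 of 31 higher and 6 lower, or 11 and 6 adjusted over the list alone. Their summed ratio was 0.683 (0.647 to 0.720), opposite in direction to the median, and 0.919 (0.854 to 0.989) without Klf17. Klf17, a transcription factor gene on chromosome 4 at 117756659 to 117765666, had 11123 reads in WT zygotes and 6963 in 2-cell embryos (0.483, 0.446 to 0.523), but 215 and 1974 T-to-C reads (7.09, 4.87 to 10.7). Summed T-to-C reads of the list gave 4.55 (3.45 to 6.11), with 1 of 16 higher and 0 lower, and the share was 2.01% in WT zygotes, 2.39% in null zygotes and 13.4% in 2-cell embryos. Klf17 carries most of this, since without it the summed ratio was 1.79 (1.13 to 2.89) and the shares 2.10%, 2.51% and 4.08%. With the filter of 50 reads, which leaves out members that reach them in 2-cell embryos alone, the median of this list was 0.08 and no longer stood apart.

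DNA damage response genes had a median of -1.09 (-0.82 with 3 members at the bound, percentile 0.3), with 3 of 33 higher and 9 lower, or 3 and 10 adjusted over the list alone. Their summed ratio was 1.11 (1.04 to 1.19), opposite in direction to the median, through H2afx, the histone variant phosphorylated at DNA breaks (4.16, 3.56 to 4.87), and was 0.643 (0.592 to 0.699) without it. With the filter of 50 reads the median was -0.99 and lay inside the central 95% of random lists. Modifiers of H3K4 and H3K27 were higher in 9 and lower in 3 of 27, with a median of -0.12 (percentile 48.0) and a summed ratio of 1.85 (1.73 to 1.97), again opposite in direction, or 1.41 (1.30 to 1.52) without Suz12. The spliceosome core had 5 of 32 higher and 8 lower, with a median of -0.28 (percentile 23.2) and a summed ratio of 1.11 (1.002 to 1.23), or 0.824 (0.735 to 0.923) without Srsf1. Srsf1, a splicing factor gene, stood at 3.97 (2.99 to 5.35). Ribosome biogenesis had 11 of 37 higher and 4 lower (median 0.49, percentile 86.3), RNA polymerase II and elongation 10 of 40 and 8 (0.27, 86.7), cytosolic ribosomal proteins 6 of 36 and 2 (0.72, or 0.66 at the bound, 92.5) and the decay machinery 7 of 34 and 6 (0.19, 78.7).

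Dcp2, Cnot8 and Ssrp1 were the members of the decay and elongation lists with higher T-to-C reads in 2-cell embryos. Dcp2, the catalytic subunit of decapping, had 31 T-to-C reads in WT zygotes and 425 in 2-cell embryos (10.6, 4.10 to 36.9), and Cnot8, a CCR4-NOT deadenylase subunit, had 6 and 185. Ssrp1, a subunit of the histone chaperone FACT, had 5 and 199, and its T-to-C share was 4.07% and 46.9%. Of 23 decay genes 2 were higher and 0 lower in T-to-C reads, with a summed ratio of 1.93 (1.47 to 2.56), or 1.39 (1.03 to 1.89) without Dcp2, and of 18 genes of RNA polymerase II and elongation 1 was higher and 0 lower. Their medians lay at percentiles 65.4 and 60.3 of random lists, so neither list stood apart. In p53 targets 1 of 10 was higher and 0 lower, or 2 and 0 adjusted over the list alone, and in abundant non-coding RNAs 3 of 9 and 0. No member passed in T-to-C reads in the lists of ribosome biogenesis, DNA damage response, H3K4 and H3K27 modifiers, immediate early genes, spliceosome core and ribosomal proteins. Of the cell markers, Cyp19a1, the granulosa cell aromatase, was lower (80 reads and 0), 1 of 6 cumulus and granulosa markers. Odf2 was higher (3.09, 2.34 to 4.15), 1 of 3 sperm markers, and Laptm5 did not pass. The list of mitochondrially encoded mRNAs had 0 members in the table.

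Against 2-cell embryos, null zygotes held more oocyte transcripts and fewer 2-cell transcripts. These groups differ in both stage and genotype. WT zygotes differed from 2-cell embryos in the same directions, so this comparison does not isolate the loss of Pabpn1l. Gdf9 was higher in T-to-C reads (52.5, 14.1 to 405), as were Bcl2l10 (40.6, 15.9 to 138), Furin (64 and 4 reads), the transporter gene Slc15a4 (47 and 1) and Cpsf4l (68 and 3). Rpph1 was lower (0.00224, upper end 0.0140), as were Prps1l3 (at least 24.8-fold), Rprl3 (at least 17.6-fold), Hist1h4d (at least 4.82-fold) and Hist2h2bb (1 and 1474 reads). In total reads Pfdn4 (at least 22.6-fold), Lypd3 (at least 22.4-fold), Aurkc (at least 20.6-fold), Xdh (at least 19.4-fold) and Atpbd4 (220 reads and 1) were higher, and Zfp352 (at least 61.1-fold), Tdpoz5 (at least 59.7-fold), Slc34a2 (at least 57.6-fold), the pantothenate kinase gene Pank3 (at least 50.0-fold) and Dub1a (at least 47.8-fold) were lower. Of 4376 genes 48 were higher and 72 lower in T-to-C reads, and of 11262 genes 1454 and 1425 in total reads. The share of higher calls in T-to-C reads was 40.0% with TMM factors, 27.4% with RLE factors and 58.9% with T-to-C reads scaled by their own total. In total reads it was 50.5% with TMM and 38.6% with RLE factors, which moved the median log2 ratio of all genes from -0.19 to -0.43. With the filter of 50 reads, 52 genes were higher and 25 lower in T-to-C reads, and 1370 and 772 in total reads. Genes that reach 50 reads in 2-cell embryos alone are left out by it, which favours higher calls here.

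Early 2-cell genes were lower in null zygotes than in 2-cell embryos in 27 of 33 members and higher in 0, or 28 and 0 adjusted over the list alone, with a median of -6.19 (-3.09 with 26 members at the bound). Oocyte-expressed genes were higher in 36 of 45 and lower in 2, with a median of 1.94 and a summed ratio of 3.28 (3.17 to 3.39). Histones were lower in 21 of 57 and higher in 1 (median -2.02, or -0.91 at the bound), p53 targets lower in 9 of 27 and higher in 0 (-1.83, or -0.53), immediate early genes lower in 7 of 16 and higher in 1, or 8 and 1 adjusted over the list alone (-3.04, or -1.05), and abundant non-coding RNAs lower in 7 of 25 and higher in 0 (-2.86, or -0.04). Genes of major genome activation were higher in 4 of 31 and lower in 7, with a median of -0.80, 0 with 4 members at the bound, and a summed ratio of 1.30 (1.21 to 1.39) in the opposite direction, or 1.05 (0.975 to 1.14) without Ldhb. With the filter of 50 reads their median was 0.30. Ribosome biogenesis genes were higher in 4 and lower in 9 of 37, or 4 and 10 adjusted over the list alone, with a median of -1.11 (-0.57 at the bound, percentile 2.70). In total reads, this list and those of DNA damage response, spliceosome, H3K4 and H3K27 modifiers, RNA polymerase II, decay machinery, ribosomal proteins and cumulus markers lay inside the central 95% of random lists. DNA damage response genes (8 of 33 higher, 2 lower) and the spliceosome core (5 of 32 and 5) had medians of 0.69 and 0.69 but summed ratios of 0.825 and 0.778, and H3K4 and H3K27 modifiers (4 of 27 and 7) and RNA polymerase II genes (2 of 40 and 7) had medians of 0.11 and 0.06 but 0.482 and 0.908. Without H2afx the sum of the DNA damage response genes gave 1.37 (1.23 to 1.53), and without Srsf1 that of the spliceosome 1.0 (0.852 to 1.17). The decay machinery had 3 of 34 higher and 8 lower, ribosomal proteins 1 of 36 and 2, sperm markers 0 of 3 and 1, and cumulus and blood markers 0. In T-to-C reads oocyte-expressed genes were higher in 10 of 36 and lower in 1, or 12 and 1 adjusted over the list alone, and histones lower in 8 of 34. Early 2-cell genes were lower in 2 of 25, or 4 adjusted over the list alone, p53 targets in 0 of 10, or 2, and in the decay machinery Dcp2 was lower and 0 of 23 were higher, or 1 adjusted over the list alone. With edgeR's exact test at the assumed variation 947 genes were called in T-to-C reads, of which 103 were among the 120, and with clumps assumed in the null column alone 257, 153 higher and 104 lower. In total reads edgeR's exact test called 3716 genes, 1293 higher and 2423 lower, of which 1752 were among the 2879 of the main test.

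Of the 155 genes that differed between null and WT zygotes, part also differed between 2-cell embryos and WT zygotes. Higher in null zygotes and in 2-cell embryos were Rn45s, Fam134c (6.08 and 9.17), Fam40a (4.47 and 4.65) and Slc36a1 (4.76 and 4.04), and lower in both were Lin52 (0.101 and 0.0994), Sec62 (0.127 and 0.139), Zfp120 (0.164 and 0.108), Txnip (0.200 and 0.128) and Cwf19l2 (0.147 and 0.227). In all 16 genes were higher in both, where 12.8 would be shared by independent lists, and 42 were lower in both, where 12.3 would be. Higher in null zygotes and lower in 2-cell embryos were 20 genes against 12.5, and the reverse held for 6 against 12.6. Part of the excess may come from the WT zygote column that both comparisons use. Across 11262 genes, which are not independent replicates, the log2 ratios of both comparisons had a Pearson r of 0.04, a Spearman rho of 0.01 and a covariance of 0.08. Unchanged columns simulated with clumps in all columns gave a mean r of 0.41 and a covariance of 0.40, and those with clumps in the null column alone 0.15 and 0.04. The observed r lay below both simulated means, while the observed covariance lay below the first and above the second. No shared effect in either direction is claimed, since these measures differ in direction under the second assumption. With the WT zygote molecules split in 2 sets, r was -0.06 and the covariance -0.13.

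The 1843 genes higher at the 2-cell stage had 263849 reads in WT zygotes and 128436 in null zygotes, a ratio of 1.1 (1.08 to 1.12), and 1.04 (1.02 to 1.05) without Rn45s. Their T-to-C reads gave 1.61 (1.48 to 1.75), and 1.36 (1.23 to 1.49) without Rn45s. The 1804 genes lower at the 2-cell stage gave 0.907 (0.899 to 0.915) in total reads and 1.14 (1.09 to 1.19) in T-to-C reads. The T-to-C share of the whole null column was itself 1.27 (1.23 to 1.34) times that of WT zygotes. Ratios above 1 in T-to-C reads are therefore not particular to these sets. The median log2 ratio of total reads was -0.18 for the higher and -0.22 for the lower set, against -0.15 for all genes, so the sum and the median of the higher set differ in direction. Both sets were chosen on the WT zygote column that also enters these ratios.

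The share of reads with a T-to-C mismatch was higher in null than in WT zygotes over the whole column. It was 3.03% (95% Clopper-Pearson interval 3.01 to 3.05) in WT zygotes, 3.86% (3.82 to 3.89) in null zygotes and 4.54% (4.52 to 4.56) in 2-cell embryos. The null-to-WT ratio was 1.27, with an interval of 1.23 to 1.34 from resampling genes, and the 2-cell-to-WT ratio was 1.5 (1.33 to 1.66). Of 163 genes with at least 1000 reads in both zygote columns 119 had a higher share in null zygotes, with a median ratio of 1.28, and of 2581 genes with at least 100 reads 1410 did (54.6%). Zbed3, a zinc finger gene chosen after its values were seen, had a share of 1.34% in WT zygotes, 1.74% in null zygotes and 10.3% in 2-cell embryos. Gdf9 had shares of 1.96%, 3.04% and 0.762%, and Bcl2l10 9.88%, 13.6% and 3.66%. For single genes, the share test called 0 of 3671 in null against WT zygotes, with 34 at an unadjusted p under 0.05. It called 128 higher and 4 lower of 3901 in 2-cell embryos against WT zygotes, and 5 higher and 51 lower of 3624 in null zygotes against 2-cell embryos. No unlabelled embryos were analysed here, so mismatches from sequencing error or sequence differences are not separated from labelled RNA.

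**Figure D3:**
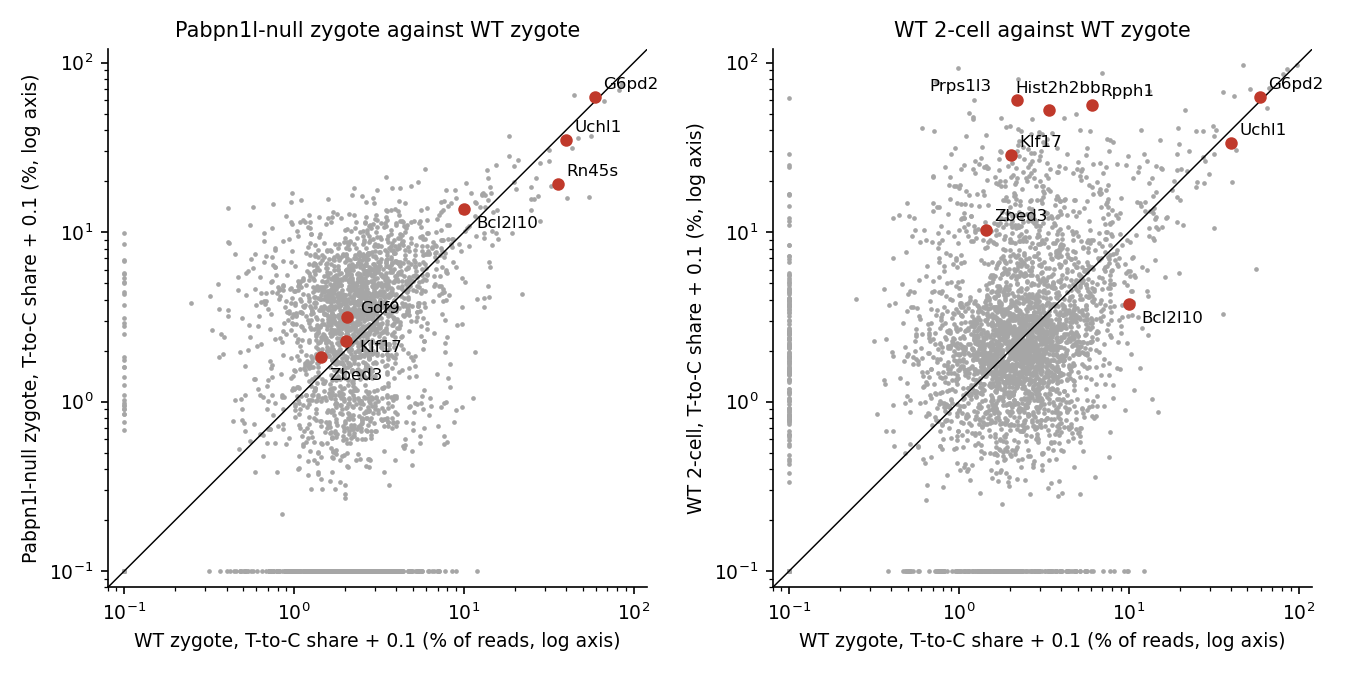
T-to-C share plus 0.1, in percent on log axes, of each gene (grey) with at least 100 reads in both columns, for null zygotes (left) and 2-cell embryos (right) against WT zygotes. The line marks equal shares and red points are named genes. Rpph1 lies at 6.0% and 56.3% on the right, and Gdf9 at 1.96% and 3.04% on the left.

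In the authors' deposited table, rows were called Positive or Negative, and 924 rows were Positive in WT zygotes, 1359 in null zygotes and 1832 in 2-cell embryos. The calls of the authors' deposited table followed 1 rule with 0 differing rows, but the limits differed between columns. In the WT columns of the authors' deposited table a row was Positive with more than 30 T-to-C reads, or with more than 20 reads of which at least 20% were T-to-C reads. For the null column of the authors' deposited table these limits were more than 15 T-to-C reads or more than 10 reads. At the WT limits the null column would hold 655 Positive rows, and at the null limits the WT zygote column 1886 and the 2-cell column 2917. With reads thinned to the null depth and judged at the null limits, the WT zygote column held a mean of 776 rows (743 to 806 in 100 draws) and the 2-cell column 1314 (1264 to 1361). The number of Positive rows in null zygotes in the authors' deposited table, 1359, was above the range of the thinned WT zygote column and inside that of the thinned 2-cell column. The thinning drew reads independently, while reads of the null column came in clumps. Drawn in clumps, the WT zygote column gave 1112 to 1231 rows, so no likeness of null zygotes to 2-cell embryos follows.

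**Figure D4:**
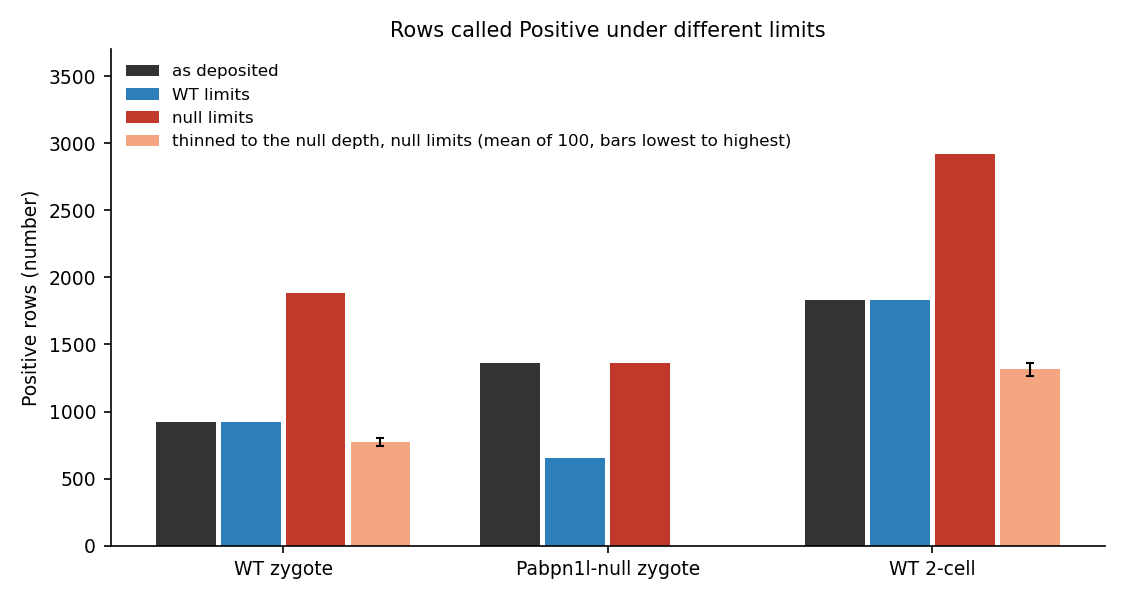
Number of rows called Positive (vertical axis) in each group (horizontal axis), as in the authors' deposited table, at the WT limits, at the null limits, and thinned to the null depth at the null limits (mean of 100 draws, bars from lowest to highest). The null column holds 1359 rows at its own limits and 655 at the WT limits, against 924 in the WT zygote column.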

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

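The count of rows with a date for a name was looked at after the table was seen, and no other test was added. In the WT zygote column these 47 rows held 4114 reads, of which 283 were T-to-C reads (6.88%). The null column held 2111 reads there, of which 123 were T-to-C reads (5.83%), and the 2-cell column 10126, of which 519 were (5.13%). Each number of T-to-C reads lies above the floor of 21 reads. The dates are days of March and September, and septin and March ubiquitin ligase genes are not named in any other row, so they are missing from every test. The rows were not assigned to genes here.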

How the results depend on the processing

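Alternatives on clumps, edgeR's exact test, adjusted p alone, distinct rows, column and T-to-C totals, the split of WT molecules and the Positive limits were chosen after the data were seen. No paired analysis was possible because the table has 1 pair of columns per group, and for the same reason no library could be left out. The cause of a change was not tested unless stated. Gene numbers below are in T-to-C reads unless total reads are named. With every read counted as 1 molecule, 783 genes (2 at 7 reads per molecule) passed in null against WT zygotes, 2158 (260) in 2-cell embryos against WT zygotes and 2026 (120) in null zygotes against 2-cell embryos, and in total reads 2670 (155), 6644 (3647) and 6889 (2879), as more molecules give smaller p values by construction. The lists apart from random ones in null against WT zygotes were then 2 (1), and the correlation of both effects was -0.0339 (0.0380), of the opposite sign. With clumps in the null column alone the numbers were 9, 2158 and 257, and in total reads 311 and 6644. edgeR's exact test at an assumed variation gave 1, 938 and 947, and in total reads 137, 2966 and 3716. The filter of 50 reads gave 87 for 2-cell embryos against WT zygotes, 2257 in total reads, and 77 for null zygotes against 2-cell embryos. By its design this filter leaves out genes that reach 50 reads in 2-cell embryos alone. Under it 2 (1), 3 (8) and 3 (7) lists stood apart. Of the calls of named genes, 42 (82) were kept, where a gene can hold several calls and genes left out by the filter count as not kept. The median of major genome activation genes in null zygotes against 2-cell embryos was 0.30 (-0.80) under this filter, the opposite sign. With no filter the correlation was 0.10, of the same sign. With WT zygote molecules split it was -0.0568, of the opposite sign. Adjusted p alone gave 305 in total reads for null against WT zygotes. Summing distinct rows gave 4 genes there, and without abundant non-coding RNAs 1, since Rn45s is one of them. Without predicted genes 3 lists stood apart there. Positive rows were 1886 in WT zygotes at the null limits (924 in the authors' deposited table), 655 in null zygotes at the WT limits (1359 in the authors' deposited table) and 2917 in 2-cell embryos at the null limits (1832 in the authors' deposited table).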

Other observations

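Gene choices in this paragraph were made after the values were seen. A class of 205 genes had a T-to-C share of at least 10% in 2-cell embryos, a pooled share under 5% in zygotes, and at least 100 reads in both zygote columns. Among its members were Ccna2, cyclin A2, with shares of 2.53% in WT zygotes, 1.52% in null zygotes and 25.2% in 2-cell embryos, and Dbf4, the activator of the replication kinase CDC7, with 2.05%, 2.53% and 19.1%. Hsf1, the heat-shock factor that is supplied by the oocyte, had 2.10%, 0% and 29.9%. Smarca2, an ATPase of the BAF remodelling complex, had 3.72%, 0.917% and 22.7%. In null zygotes Hsf1 had 0 T-to-C reads of 113, Smarca2 1 of 109 and Ccna2 3 of 197. Each of these T-to-C counts is below the 7 reads counted as 1 molecule. A lower share in null than in WT zygotes is therefore not shown for these genes. The pluripotency factor gene Sall4 had 2.57%, 4.91% and 15.5%, the stress kinase gene Mapk8 4.57%, 3.31% and 13.3%, the phosphatase gene Dusp7 1.79%, 2.93% and 11.8%, and the oocyte gene Oog3 2.29%, 2.51% and 22.7%. Total reads of Oog3 were 4288 in WT zygotes and 4802 in 2-cell embryos, so the difference in share was not visible in the total.

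The higher T-to-C share in null zygotes was set against 3 explanations, of which the test on oocyte-expressed genes and 2 other choices of the 2-cell class were added after the result was seen. Earlier transcription of 2-cell genes predicted a larger rise in the 205 genes above than in 2376 others. The ratio of both share ratios was 0.928 (0.848 to 1.02), so no larger rise was seen. This class was limited on a zygote share that includes the null column, which can lower the ratio. Chosen without the null column, the class gave 1.03 (0.933 to 1.15), which leaves a small rise open. That choice limits the WT zygote share, the divisor of the share ratio, which can raise the ratio. Chosen on the 2-cell share alone it gave 0.730 (0.665 to 0.806), but can then hold genes with a high share in every column. Genes with few or no zygote reads are not among the 205, so this explanation was not decided. Different transcripts in both columns are excluded as the sole cause, since the ratio was 1.25 (1.21 to 1.29) with each gene weighted by its WT zygote reads. Oocyte-expressed genes as a group, largely stored RNA, had a ratio of 1.25 (1.06 to 1.47), against 1.27 for genes outside the list, which is consistent with a rise over the whole library. Labelling or alkylation that differed between libraries could give such a rise, as could broad transcription, and without an unlabelled control these were not separated.

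For the larger number of Positive rows in null zygotes, 1359 in the authors' deposited table, the tests were written before their results were seen, other than the one on clumps and the null share together, which had no written prediction. Lower limits and depth alone are excluded, since WT zygote reads thinned to the null depth gave at most 806 Positive rows at the null limits. A library-wide rise in share was not the whole of it, since null reads thinned to the WT share gave 1.24 (1.22 to 1.28) times the thinned WT zygote number. WT zygote reads drawn in clumps gave at most 1231 rows, short of the number in the authors' deposited table. With clumps and the null share together, the simulated range of 1409 to 1578 lay above it, so clumped reads may account for part of the rows and this was not settled.

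Both tests on genes with a high share everywhere were chosen after the values were seen. In 33 genes at least 20% of reads had a T-to-C mismatch in all 3 columns, among them Uchl1, a neuronal and oocyte ubiquitin hydrolase gene (39.7%, 34.7% and 33.3% in WT zygotes, null zygotes and 2-cell embryos), G6pd2, a retrocopy of G6pdx (59.1%, 62.5% and 62.5%), and Csl (85.5%, 76.1% and 91.2%). Their median 2-cell-to-WT share ratio was 1.05 (0.996 to 1.12) and their median null-to-WT ratio 1.02 (0.872 to 1.16). The choice on all 3 columns holds both ratios near 1, so a sequence difference, reads of a related copy and labelling cannot be told apart here. These genes held 6.77%, 5.13% and 3.70% of T-to-C reads in WT zygotes, null zygotes and 2-cell embryos.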
